A study of Sphingomonas sp. ATCC 31555 with 3 samples.

How the data were processed

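The series holds 3 samples of *Sphingomonas* sp. ATCC 31555, 1 each from inorganic, organic and complex nitrogen medium, with groups taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and column purification, polyadenylated RNA was isolated, and cDNA was sequenced on an Illumina Genome Analyzer. The extraction text names a plant tissue as its RNA source, which does not match the labelled organism, so details of extraction are uncertain. The assembler, gene finder, aligner, protein database release and match threshold are not given in the sources used here. Which libraries, or what other sequence, the contigs were assembled from is likewise not given.

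The authors deposited a single table of 9 columns, which per the file headers hold an identifier, a length and a protein match for each unigene, and numbered reads and RPKM. A unigene is an entry of the authors' assembly. No label holds a number for a library, and column order is no basis for assigning media. The 6 per-sample columns (3 of read counts and 3 of RPKM, per the file headers) were thus used in no step. Depth per library is therefore not reported, and no fold change, expression level or test between media was computed. This left out what had been planned before the data were examined: the counts of genes at least 2-fold apart between media, the place of the complex medium between the others, and the median change of each gene list.

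The lengths deposited by the authors are in bases. Contig, open reading frame number, start and end were read from the identifier, counted from 1 on the authors' contigs, and an identifier whose first coordinate is the larger was read as reverse. The length equalled the span of the coordinates in 3441 open reading frames and differed in 24. Numbers missing from the series of open reading frames on a contig (1122 of 4587) have no unigene analysed here, and what they stand for was not tested. Product, organism and gene symbol were read from the protein match (TrEMBL for 3226 unigenes, Swiss-Prot for 45) and are the authors' annotation, not tested against sequence. The genus of the best match was placed by hand into sphingomonads, other bacteria or archaea, rodents, bovines, other mammals, other eukaryotes or unplaced.

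The 31 gene lists, each a pattern for symbols and a pattern for product descriptions, were fixed before the data were examined, and a unigene was a member if either matched. They held 775 unigenes, 28 of them in more than 1 list. The rule for named genes was fixed at the same time. Its part on expression could not be applied, and its other part names every member of the lists for sphingan synthesis and for nitrate and ammonium assimilation. Examples from other lists, and genes outside the lists, were chosen after the annotation was seen. An item among the matches outside the bacteria is not reported here.

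Whether members of a list lie side by side was tested by counting pairs of members that follow each other by open reading frame number on a contig. The count was compared with 100000 random draws of as many open reading frames from the 3045 with a protein match (one-sided permutation test, Benjamini-Hochberg adjustment over the 29 lists with at least 4 placed members). The test was chosen after the table was seen. It asks about position in the assembly and says nothing on expression, and genes that share an operon are not independent. On simulated lists of 20 members over the same 3045 unigenes with 2000 draws, 200 of 200 lists with a planted run of 5 neighbours and 2 of 200 random lists had p under 0.05. This checks the calculation only. The planted runs lay far above random counts by design, and the random lists came from the pool that the test draws from. Lists called on 1 pair, such as that for the molybdenum cofactor, were not simulated.

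Alternatives were membership by product description alone, planned beforehand, and, chosen after seeing the data, unigenes of at least 300 bases, open reading frames alone, matches to named proteins alone, consecutive open reading frame numbers alone, and neighbours with a shared best match not counted. Shares were given Wilson or exact 95% intervals, which cover counting error alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.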

Results

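The study concerned welan gum, an exopolysaccharide of the sphingan family that *Sphingomonas* sp. ATCC 31555 secretes, and asked how the nitrogen source of the medium bears on its production. RNA was sequenced from cultures in 3 fermentation media, with 1 library per medium. The inorganic medium held 4.0 g/L sodium nitrate, the organic medium held 4.0 g/L beef extract, and the complex medium held 1.5 g/L sodium nitrate with 2.5 g/L beef extract. Cells were grown for 12 h at 37 °C, per the labels' protocols. The deposited table numbers its libraries 1, 2 and 3, and no label ties a number to a medium. Its 6 columns of reads and RPKM were therefore not used here, so expression was not compared between media and sequencing depth per medium is not reported. The results below describe the genes in the table: where they lie in the assembly, which proteins they match, and how the genes for gum synthesis and nitrogen assimilation are arranged.

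The table listed 3899 unigenes, of which 3465 were predicted open reading frames placed by coordinates on 226 contigs and 434 were contigs listed whole. The open reading frames had a median coding length of 744 bases (quartiles 381 and 1212), and summed to 3.09 Mb. Their lengths were multiples of 3 in 99.7% of cases, against 34.8% of the contigs listed whole, whose median length was 249 bases. The longest contig reached coordinate 77127, and the highest coordinates of all contigs summed to 3.87 Mb. Forward and reverse open reading frames numbered 1789 and 1676. A protein match was given for 3045 open reading frames (87.9%) and 226 contigs listed whole (52.1%). Of all 3271 matched unigenes, 999 (30.5%) matched a protein with no described function.

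Most unigenes matched proteins of sphingomonads, the family of alphaproteobacteria to which the strain belongs. Among the matched open reading frames 2430 (79.8%) had a sphingomonad as the organism of their best match. The organism named most often was *Sphingomonas* sp. S17, with 762 unigenes, followed by *S. sanxanigenens* NX02 with 269 and *Sphingomonas* sp. MM-1 with 161. Strains known for sphingan gums gave 50 best matches. These comprised 29 to *S. elodea*, the gellan producer, 12 to *Sphingomonas* sp. S88, 5 to the diutan producer *Sphingomonas* sp. ATCC 53159, 3 to *Alcaligenes* sp. NX-3 and 1 to *Sphingomonas* sp. S7. Of the 50 matches, 24 lay on Contig5.

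The contigs listed whole had a different makeup. Only 37 of their 226 matches (16.4%) were to sphingomonads and 55 (24.3%) to other bacteria. Rodents gave 50 best matches, cattle and their relatives 3, other mammals 49 and other eukaryotes 27. Mammals thus made up 45.1% of the matched contigs listed whole (Wilson 95% interval 38.8% to 51.7%), against 1 of 3045 matched open reading frames (0.0328%; Fisher's exact test, two-sided, p = 2.9e-128). These shares count table entries, not reads, and rest on the best matches as deposited. The entries are not independent: many open reading frames shared a contig (median 10 per contig), and several contigs listed whole matched the same gene. The Fisher p-value therefore overstates the evidence.

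**Figure D1:**
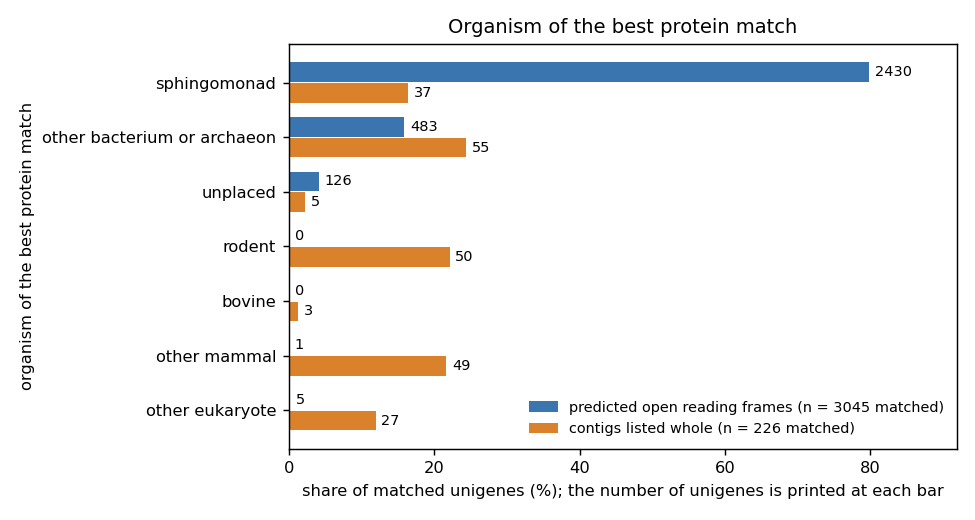
Organism of the best protein match as a share (%) of the matched unigenes, for 3045 predicted open reading frames (blue) and 226 contigs listed whole (orange), with the number of unigenes at each bar. Sphingomonads take 79.8% of the former and 16.4% of the latter, in which rodents (50) and other mammals (49) are nearly as frequent as bacteria other than sphingomonads (55).

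Genes for sphingan synthesis lay mainly in a single region of the assembly. The list for welan and sphingan synthesis had 23 members, of which 19 stood on Contig5 between positions 23901 and 50810. This stretch of 26910 bases held 23 unigenes, 15 forward and 8 reverse, and 21 of them had their best match in a sphingan-producing strain. The list members set the bounds of the stretch, and most of them entered by symbols given in such strains. The 21 matches are therefore largely fixed by the list's wording. By open reading frame number along the contigs, the list made 14 neighbouring pairs, against a mean of 0.143 in random lists of the same size (one-sided permutation test over 100000 draws, p = 1.0e-05, the smallest the draws can give; Benjamini-Hochberg adjusted p = 2.1e-05 over 29 lists). Much of this count rests on gene symbols taken over from the sphingan clusters of related strains, since by product description alone the list had 8 members and 1 neighbouring pair (adjusted permutation p = 0.02). That pair was dpsC and dpsE, both described as diutan polysaccharide export proteins, so it too rests on names from such a cluster. Counting only consecutive open reading frame numbers gave 9 pairs.

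From its lower end, the region opened with the reverse unigenes spsG (23901 to 25538), spsS (25548 to 26828) and spsR (26906 to 28933). After 1185 bases without a unigene analysed here came gelI on the reverse strand (30119 to 31045). The glycosyl transferase unigenes spsK (31208 to 32206) and spsL (32188 to 33069), whose products attach sugars to the growing repeat unit, were forward and overlapped by 19 bases. They were followed by spsJ in reverse (33086 to 34093) and by gelJ (34094 to 34621) and gelF (35095 to 36363) forward. A short spsD unigene (37119 to 37277) preceded dpsC (37312 to 38661) and dpsE (38661 to 39365), both annotated as diutan polysaccharide export proteins and sharing 1 base. An uncharacterized protein matched to strain S88 (39511 to 40257) and gelN (40262 to 40951) came next. The reverse pair atrD (40999 to 42318) and atrB (42390 to 44354) bears symbols of transporter genes described in sphingan clusters.

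The upper end of the region held the first sugar transferase of the pathway and the genes for its rhamnose donor. Between atrB and these genes stood a 504-base unigene matched to an uncharacterized *Janthinobacterium* protein (44860 to 45363) and an unmatched unigene of 213 bases (45751 to 45963). The gelB unigene (46021 to 47325) was annotated as glucosyl-isoprenylphosphate transferase, which loads glucose onto the lipid carrier. It was followed by glucose-1-phosphate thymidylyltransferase (47492 to 48316), rhsC (48448 to 48879), rhsB (48883 to 49944) and rmlD (49944 to 50810), all forward. Enzymes of these 4 kinds convert glucose 1-phosphate into dTDP-L-rhamnose. The rhsC unigene, annotated as an epimerase, fell outside the list's wording and was named after the table was seen, as was urf31.4 (50975 to 51112, reverse), the next unigene. The last position annotated on Contig5 was 51324.

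**Figure D2:**
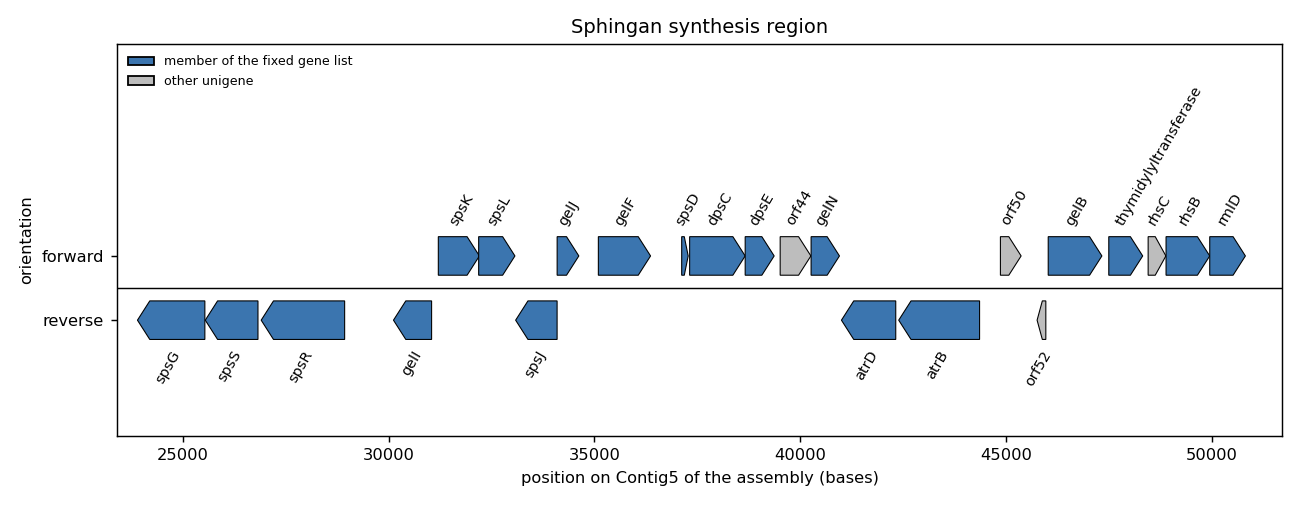
Map of the sphingan synthesis region on Contig5, positions 23901 to 50810 in bases, with each unigene drawn to scale as an arrow in its orientation (forward above, reverse below). The 19 members of the list are blue and the other unigenes grey; the 15 forward unigenes include the run from gelB to rmlD.

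Genes for other precursors and for regulation lay outside this region. The other 4 members were a gelA unigene annotated as a gellan biosynthesis regulator (Contig135, 16120 to 18504, reverse), phosphoglucomutase (Contig34, 7143 to 8531, forward), UDP-glucose dehydrogenase (Contig119, 6256 to 7398, forward) and a polysaccharide biosynthesis protein matched to *Novosphingobium nitrogenifigens* (Contig120, 8645 to 10153, reverse). Phosphoglucomutase supplies glucose 1-phosphate, and UDP-glucose dehydrogenase makes UDP-glucuronate, a sugar donor of sphingans. A UDP-glucose pyrophosphorylase matched to *Alcaligenes* sp. NX-3 (Contig10, 7035 to 7904, forward), which makes UDP-glucose, was not caught by the list's wording and was also named after the table was seen.

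Nitrate assimilation genes formed a shorter run on Contig14. The list for nitrate and ammonium assimilation had 14 members on 8 contigs, with 4 of them on Contig14 between positions 15603 and 25999. A nitrate transporter (15603 to 16817) was followed by a transporter of the major facilitator superfamily and an uncharacterized protein, neither of them in the list. Then came nasB, a putative nitrite reductase (20581 to 23082), a second nitrite reductase unigene of 327 bases (23088 to 23414) and nasA, a putative nitrate reductase (23492 to 25999). All 6 unigenes of this stretch were forward. Nitrate reductase and nitrite reductase together reduce nitrate to ammonium, the form that enters amino acids. The nasA and nasB unigenes had their best matches in *S. elodea*.

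Ammonium uptake and assimilation genes were found on other contigs. A nitrogen regulatory protein P-II (12977 to 13315) directly preceded an ammonium transporter (13330 to 14754) on Contig61, both forward. Glutamine synthetase (2697 to 4079), which fixes ammonium onto glutamate, lay beside a further P-II unigene (4205 to 4543) on Contig59, both reverse. The glnD unigene, for the uridylyltransferase that modifies P-II, was on Contig92 (5043 to 7790, forward). A bacterial NAD-glutamate dehydrogenase of 4623 bases lay on Contig110 (4763 to 9385, forward), and a formate/nitrite transporter on Contig10 (37860 to 38630, forward). Whether this dehydrogenase fixes or releases ammonium is not given by its annotation. The list made 4 neighbouring pairs against a random mean of 0.0504 (one-sided permutation test, p = 1.0e-05, the smallest the draws can give; adjusted permutation p = 2.1e-05). The remaining 3 members need not belong to nitrogen assimilation: a protein with a nitrite and sulphite reductase domain (Contig65, 20433 to 22067, reverse), a permease annotated for nitrate, sulfonate or bicarbonate (Contig90, 40845 to 41660, reverse) and folylpolyglutamate synthase (Contig90, 10642 to 11958, reverse). The last, which adds glutamate to folate, entered through the words glutamate synthase in its name. No other member of the list was annotated as a glutamate synthase.

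**Figure D3:**
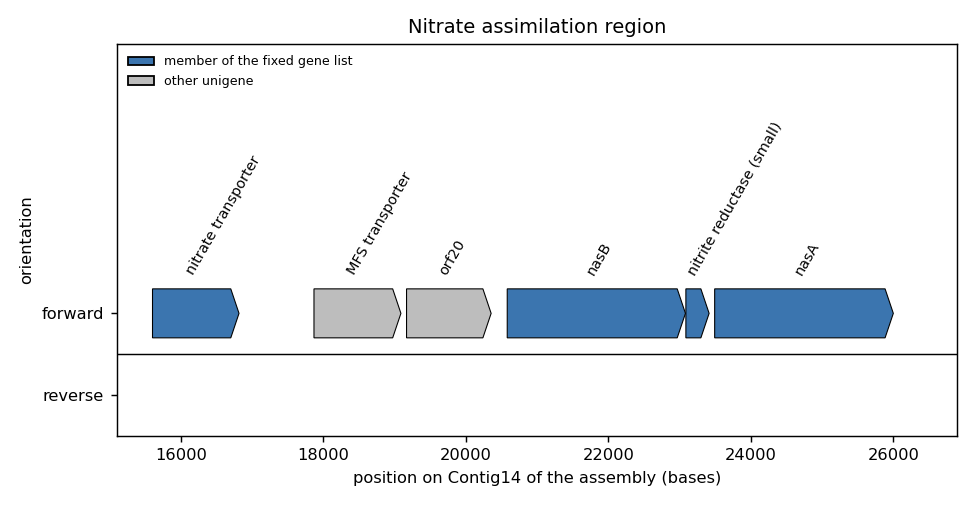
Map of the nitrate assimilation region on Contig14, positions 15603 to 25999 in bases, with each unigene drawn to scale as an arrow in its orientation. All 6 unigenes are forward; the 4 list members (blue) are the nitrate transporter, nasB, the 327-base nitrite reductase unigene and nasA, and grey marks the other unigenes.

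Nitrate reductase carries a molybdenum cofactor. The molybdenum cofactor list had 9 members on 8 contigs, among them moaA, moaC and mobA, with 1 neighbouring pair formed by 2 subunits of a molybdate transporter on Contig28 (adjusted permutation p = 0.026). Sulfate assimilation had 3 members, too few for the test. The cysD unigene and a bifunctional sulfate adenylyltransferase subunit lay side by side on Contig119 (7518 to 10351), next to UDP-glucose dehydrogenase.

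Central carbon metabolism was covered by 3 lists. The glycolysis, Entner-Doudoroff and pentose phosphate list had 28 members, 1 of them with a eukaryotic best match, and made 6 neighbouring pairs (adjusted permutation p = 2.1e-05). On Contig76 (1753 to 7682) zwf, pgl, edd, glk and eda, which take glucose through the Entner-Doudoroff route, stood together. The tricarboxylic acid cycle and glyoxylate shunt list had 16 members and 3 pairs (adjusted permutation p = 5.1e-05). Of these pairs, 2 were formed by sdhA, sdhD and sdhC, which followed each other on Contig53 (8889 to 11498, reverse). Other members, among them mdh, a succinyl-CoA ligase subunit, sucA and acnA, lay on Contig17. This list also caught leuB, an enzyme of leucine synthesis. The list for sucrose and sugar uptake and cleavage had 4 members and no pair (adjusted permutation p = 1): a levansucrase on Contig58, 2 alpha-glucosidases, and a DNA invertase, a recombinase that entered by its name.

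The respiratory chain and the ribosomal proteins made the most neighbouring pairs of the lists tested, 26 and 24. The respiratory chain and ATP synthase list had 60 members, of which 10 had a eukaryotic best match and 50 did not. Its 26 pairs stood against a random mean of 0.634 (adjusted permutation p = 2.1e-05), and 13 members, among them nuoA to nuoI and nuoK, nuoN, lay on Contig1 (24342 to 39391). Ribosomal proteins had 54 members, 2 with a eukaryotic best match, and 24 pairs against 0.746 (adjusted permutation p = 2.1e-05), with 22 members on Contig23 (1503 to 17702). RNA polymerase and translation factors had 18 members and 2 pairs (adjusted permutation p = 0.0034), rpoB and rpoC being on Contig28, and no pair with consecutive numbers alone (adjusted permutation p = 1). The 21 aminoacyl-tRNA synthetase unigenes made no pair (adjusted permutation p = 1). The list meant for ribosomal and transfer RNA caught 2 unigenes, both of them enzymes that modify tRNA, and was not tested.

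Biosynthetic lists also had neighbours in excess of random lists, though to different degrees. Vitamin and cofactor biosynthesis had 43 members and 15 pairs, with 13 members on Contig146 (21081 to 41036), most of them precorrin and cobalamin genes such as cobB, cobG and cobN (adjusted permutation p = 2.1e-05). Cell division and peptidoglycan synthesis had 27 members and 12 pairs, with 15 members on Contig47, among them murC to murG, ftsA, ftsQ, ftsW and ftsZ (adjusted permutation p = 2.1e-05). The 62 members for amino acid biosynthesis were spread over 48 contigs and made 8 pairs against 1.06 (adjusted permutation p = 2.1e-05). The wording of this list also caught genes of other processes. Among them were metG, a methionine-tRNA ligase, and murE, which also stood in the tRNA synthetase and cell division lists. Purine and pyrimidine synthesis had 22 members and 3 pairs (adjusted permutation p = 5.0e-04), and polyhydroxyalkanoate metabolism 5 members and 1 pair (adjusted permutation p = 0.0079). The carotenoid and isoprenoid list had 15 members and 2 pairs (adjusted permutation p = 0.0023), which were crtY with crtI on Contig112 and 2 dxs unigenes of 144 and 120 bases on First_Contig6. The crtB unigene stood near the former pair, with an uncharacterized unigene in between. The 2 dxs unigenes overlapped and had the same symbol and product, so they may be parts of 1 gene. Their best matches were in different organisms, so the alternative without shared best matches still counted them. Fatty acid degradation had 14 members and 3 pairs (adjusted permutation p = 3.6e-05), and fatty acid synthesis 13 members and 1 pair (adjusted permutation p = 0.044). The carotenoid call was lost with consecutive numbers alone (adjusted permutation p = 0.052) and, like the call for fatty acid synthesis, among unigenes of at least 300 bases (adjusted permutation p = 0.054 and 1). The 23 members for amino acid and peptide degradation made 1 pair, which did not pass the test (adjusted permutation p = 0.14).

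Among transport, surface and stress lists, those for TonB-dependent receptors and for iron did not pass the test. The receptor list had 70 members, and the 64 that were placed open reading frames stood on 54 contigs. Most members were annotated as receptors, outer membrane proteins that import large or scarce nutrients. However, the list also caught TonB and ExbD/TolR proteins of the system that energizes them. It made 3 pairs against 1.13 (adjusted permutation p = 0.12), and 1 pair when neighbours with a shared best match were not counted (adjusted permutation p = 0.76). The 10 iron genes made none (adjusted permutation p = 1). Flagella, chemotaxis and pili had 54 members and 12 pairs, efflux and multidrug transport 32 members and 12 pairs, and protein secretion 33 members and 9 pairs (each with adjusted permutation p = 2.1e-05). The list for phosphate uptake and polyphosphate had 38 members and 6 pairs (adjusted permutation p = 3.6e-05), with pstC, phoU and phoB on Contig124. Its pattern for PhoR, read without regard to case, also caught products worded phosphoribosyl. The trpF and hisE unigenes, of amino acid biosynthesis, entered in this way. Its members and pairs thus need not concern phosphate uptake. Conjugation and type IV secretion had 8 members and 4 pairs, transposases and phage genes 33 members and 7 pairs, and heat shock and proteolysis 22 members and 5 pairs (each with adjusted permutation p = 2.1e-05). Oxidative and general stress had 29 members and 2 pairs (adjusted permutation p = 0.026). In all, 24 of the 29 lists tested had more neighbours than random lists at an adjusted p under 0.05. Membership followed symbols and product wording, and 20 memberships in 8 lists belonged to unigenes with a eukaryotic best match.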

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

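Of these alternatives only membership by product description was planned; the others were chosen after seeing the data. By product description alone, the sphingan list fell from 23 members to 8, since the products of the other members lack the list's wording; the other 30 lists stayed within 1.5 times their size. All 31 lists did so among unigenes of at least 300 bases. The neighbour test called 24 lists by product description alone, and 24 when the 22 pairs of neighbours with a shared best match were not counted, in both cases the 24 called before. It called 22 of those 24 with consecutive numbers alone, losing RNA polymerase and translation factors (adjusted permutation p = 1) and carotenoid and isoprenoid synthesis (adjusted permutation p = 0.052). It also called 22 with unigenes of at least 300 bases, losing carotenoid and isoprenoid (adjusted permutation p = 0.054) and fatty acid synthesis (adjusted permutation p = 1), where fewer unigenes were tested. The sphingan and nitrogen lists passed under all 4 alternatives, the former with 1 to 14 pairs and the latter with 4. For the sphingan list this is no independent support. Its symbols, and the products of the 1 pair left by description, were named from sphingan clusters of related strains. The mammalian share of matched contigs listed whole was 50% among named proteins and 46.3% at 300 bases or more, inside the interval of the main value. The planned pseudocounts, expression filters, scalings and 4-fold threshold were not run, because no column of values could be tied to a medium. No paired analysis was possible because each medium had 1 library. Depth per library was not used.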

Other observations

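Neighbouring open reading frames with consecutive numbers were packed closely. In the same orientation, 1556 such pairs had a median of 64 bases between them, against 42 for 324 convergent pairs and 182 for 462 divergent pairs. An overlap of exactly 4 bases, as when a start codon overlaps the preceding stop codon, occurred in 248 pairs of the same orientation (15.9%), in 16 convergent pairs (4.94%) and in 0 divergent pairs. An overlap of 1 base, as between dpsC and dpsE, occurred in 56 pairs of the same orientation (3.60%) and in 0 of the others.

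Bacteria other than sphingomonads on the contigs listed whole included *Ralstonia* with 8 contigs and *Vibrio* and *Clostridium* with 4 each. Among open reading frames, fragments matched to urf31.4 occurred on Contig5 and again on Contig68 (6563 to 6715 and 6769 to 7224, both reverse), and proS, for prolyl-tRNA synthetase, was represented by 2 unigenes on Contig5 (16491 to 16808 and 19930 to 21462, both reverse).

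All 4 tests on mammalian matches were chosen after those matches were seen. In all, 103 unigenes had a mammalian best match, with a median length of 306 bases; 50 of these matches were to rodents, 18 to human, 13 to mitochondrially encoded proteins and 30 to proteins of no described function. The tables argue against bovine RNA from the beef extract as the main source, since 2.15% of the distinct mammalian proteins matched (2 of 93, exact 95% upper bound 7.55%) were bovine, provided that the database searched, which is not given, held the bovine proteins. They also argue against chance matches of *Sphingomonas* sequence as the source of the rodent matches as a set, since among those with a gene symbol 44.4% (20 of 45, exact 95% lower bound 29.6%) shared it with another, where chance matches would fall on different genes. Among matches to bovines and other mammals that had a symbol, 4 of 24 shared it. For the other mammals chance matches to short sequence stay open. Without the rodent matches, the mammalian share of matched contigs listed whole was 21.7% at 300 bases or more and 36.6% below (Fisher's exact test, two-sided, p = 0.033). True mammalian sequence on short contigs could give such a contrast too, so it cannot decide the question. Several of the mammalian contigs matched the same gene or clone, while the p-value treats them as independent. Not all of these contigs were short. Contig345 and Contig352, of 1297 and 917 bases, matched the same *Macaca fascicularis* clone.

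For the rodent part, RNA or cDNA from rodent liver, from another sample, may be a source: a list of liver genes matched 25 unigenes, all with rodent best matches, while the lists for skeletal muscle, brain, blood, pancreas, kidney, lymphoid tissue and testis each matched 0. Because the liver list was written after such names were seen, this contrast cannot decide the question. No biological explanation was tested.

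The 25 liver-list unigenes included Alb (5), Serpina3k (3), Apoe, Serpina1b, Tf and Hpx (2 each), Fabp1, Apoa1, Apob, Sepp1, Mup2 and Mup8 (1 each), and 2 without a symbol. Alb encodes albumin, the main protein secreted by liver. The liver list was written with such names already in view, and it holds rodent gene names, so neither its match count nor the share of rodents among its matches is independent of its choice. Outside the mammalian matches its patterns caught 2 unigenes. Read levels of these unigenes, and whether they differ between media, were not analysed here.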
